A study of Mus musculus with 12 samples.

How the data were processed

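The samples were 12 RNA sequencing libraries from the back skin of male mice aged postnatal day 26 to 27, when hair follicles enter a new growth phase. The mice carried a green fluorescent reporter driven by Sox2 and a red fluorescent reporter driven by the smooth muscle actin promoter. Skin was digested with dispase and collagenase, and cells were sorted by flow cytometry on the reporters and on antibodies that the labels do not name. The 4 sorted populations are hair follicle dermal stem cells, dermal sheath, dermal papilla and interfollicular dermis, with 3 libraries each. According to the labels, messenger RNA was captured on oligo(dT) beads and sequenced as SOLiD libraries.

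The authors deposited one table of FPKM values, that is, fragments per kilobase of transcript scaled to the mapped fragments of the library, with one column per library and 24692 entries, one per annotated gene. The labels list TopHat2 2.0.13, SAMtools and Cufflinks 2.2.1 and the mm10 build, without roles, parameters or an annotation, and state no further scaling between libraries. The table holds 24162 distinct gene symbols, 804 entries that share a symbol with another (7 of those tested) and 1222 entries without an Entrez identifier. Raw counts were not used here, so the number of reads behind a value is unknown and no counting interval is given. A relative depth was taken from genes under 0.3 FPKM in every library and above 0 in both libraries compared. It was the inverse of the commonest ratio of a library's value to that in dermal stem cells replicate 2, on the assumption that genes at that ratio have equal reads in both. It ran from 0.633 in dermal papilla replicate 4 to 1.93 in interfollicular dermis replicate 6, relative to dermal stem cells replicate 2, a 3.05-fold range. The commonest ratio held 26.2% to 35.6% of the genes it was read from, so these depths are approximate.

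Genes with at least 1 FPKM in at least 3 libraries were tested, 12774 in all. Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, as 4 population means in one linear model with empirical Bayes moderation and a mean-variance trend. The model had 8 residual degrees of freedom and a prior worth 4.61 more. A moderated F test asked which genes differed among the 4 populations, and 7 contrasts compared populations or, for follicle mesenchyme against interfollicular dermis, the mean of 3 populations against the fourth. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. A gene counted as specific to a population when it passed and was higher in each of the 3 contrasts with the other populations. All tests are two-sided. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

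The tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a choice is said to have been made after seeing the data. The 32 lists cover markers of the sorted populations, signalling pathways, extracellular matrix, proliferation, positional identity, stress and markers of other cell types in skin. The list of the 2 reporter genes is too short for a list test, which needs 3 tested members, and the other 31 were tested in 4 contrasts with camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes. The 124 list tests were adjusted together. Each was repeated with an inter-gene correlation estimated from the residuals, and with fry, which tests whether the genes of a list move on balance one way. Members that passed were counted with adjustment over all genes and also adjusted over the list alone, and where the second count is not printed it equals the first. Among list members, 3 were matched by an older symbol and 1 was not found.

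Named genes were the 10 with the largest log2 fold change in each direction among those that passed, had every library of the higher group above every library of the lower group and averaged at least 5 FPKM in the higher group. Up to 4 of the most changed members of each list, all tested R-spondin and LGR genes and 8 genes per specific count were added. The result of one gene that this rule names is not reported here. A separation of all 3 from all 3 libraries arises by chance in 10% of orderings. The pools from which the named genes were ranked held 221 genes higher and 656 lower for dermal papilla against dermal stem cells, 2640 and 1837 for dermal sheath against dermal stem cells, 1448 and 3392 for dermal papilla against dermal sheath, and 173 and 179 for follicle mesenchyme against interfollicular dermis. Gene positions are those of GRCm38.p6, matched by Entrez identifier for 12399 of the tested genes. The authors' annotation may differ.

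The FPKM table lists values of exactly 0 for some genes that are abundant elsewhere. Among tested genes, 408 had a 0 in at least one library and more than 10 FPKM in another, and in 17 of them each population was either at 0 throughout or above 0 throughout. Of such genes, 6 were at 0 in all dermal stem cell and dermal papilla libraries and above 0 in all others. The reverse held for 4. For named genes listed at 0 in a whole population, library values are given in place of a fold change.

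Replicate numbers in the sample titles were checked against the data. Across genes, the deviations of dermal stem cells and dermal papilla libraries from their population means correlated at 0.306, 0.241 and 0.389 for libraries with the same number and at -0.333 to 0.125 for the others, so the numbers were taken, from the data, to pair these samples, and a fit of these 6 libraries with the number as a block is given beside that comparison. Genes are not independent replicates in such a correlation, and the deviations of 3 libraries from their mean sum to 0, so the pairing remains an assumption. Other pairs of populations share at most 2 numbers, and their correlations at the same number ran from -0.272 to 0.294. The titles of the dermal sheath libraries carry the numbers 4 and 5 and, for one library with a slightly different prefix, 1.

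The procedure was tested on simulated data of 12774 genes with 200 changed between dermal papilla and dermal stem cells. It recovered 21% of 2-fold and 76% of 4-fold changes, gave 0 calls with the wrong sign and called 7 unchanged genes. The changed genes were drawn only from genes above a minimum mean value, so recovery among the lowest tested genes was not measured. The mean fitted log2 fold changes were 1.01 and 1.93. Camera gave p = 1.4e-34 for a simulated raised list and p = 0.79 for an unchanged one (6.7e-07 and 0.77 with an estimated correlation, 1.4e-08 and 0.85 with fry). The simulated genes were drawn independently of each other, while the median correlation estimated in the data was 0.222. The simulation therefore cannot tell how the list tests behave with correlated genes.

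The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a mean FPKM of at least 5, genes above 0 in every library, quantile normalization, median-of-ratios scaling, array weights, no trend, the replicate number as a block, only the groups compared, and leaving out each library in turn. Chosen after seeing the data were the filter on values of 0 and fits without dermal stem cells replicates 1 and 2 together, without dermal papilla replicates 1 and 2 together, and with follicle mesenchyme as dermal stem cells and dermal papilla only.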

Results

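Gene expression was measured by RNA sequencing in 4 cell populations sorted from the back skin of mice at the start of a hair growth cycle, with 3 libraries per population. Dermal stem cells are a mesenchymal population around the follicle base whose progeny include the dermal sheath. The dermal sheath wraps the follicle, the dermal papilla is the cluster of signalling cells at its base, and the interfollicular dermis is the connective tissue between follicles. The sum of FPKM per library ran from 181683 (interfollicular dermis replicate 6) to 262695 (dermal stem cells replicate 1). Between 10711 and 11810 genes per library reached 1 FPKM, and 30.14% to 41.92% of genes were listed at 0. The 10 most abundant genes held from 3.53% of the total (dermal sheath replicate 1) to 16.4% (dermal papilla replicate 1). In the text below, values are mean FPKM ± SD over the 3 libraries of a population, fold changes are on the log2 scale, and p-values for genes are adjusted p-values from limma.

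The 12 libraries fell into 2 pairs of similar populations. Dermal stem cells resembled dermal papilla, with a mean correlation across genes of 0.842 (range 0.811 to 0.878), and the libraries labelled dermal sheath resembled those labelled interfollicular dermis (0.884, range 0.864 to 0.91). Across the pairs the mean correlations were 0.627 to 0.678. Within populations they were 0.923 for dermal stem cells (range 0.896 to 0.955), 0.928 for dermal sheath (0.92 to 0.932), 0.872 for dermal papilla (0.843 to 0.918) and 0.918 for interfollicular dermis (0.9 to 0.944). The dermal papilla range overlaps that between dermal papilla and dermal stem cells. Dermal papilla replicate 4 correlated at 0.8525 with dermal stem cells replicate 4 and at 0.8427 with dermal papilla replicate 2. Genes are not independent replicates in these correlations. The first principal component held 55.4% of the variance and placed dermal stem cells and dermal papilla between -79.53 and -57.08, and dermal sheath and interfollicular dermis between 44.39 and 86.37. The second, with 12%, placed dermal papilla at 35.19 to 41.9 and dermal stem cells at -44.09 to -38.18. Among the 4 populations 7256 genes differed by the F test, 56.8% of those tested.

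**Figure D1:**
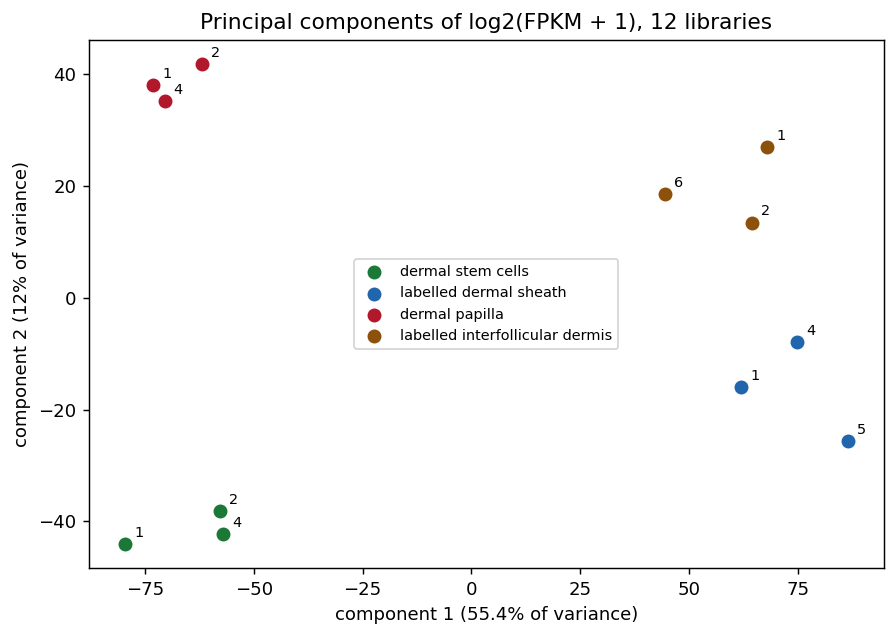
Principal components 1 and 2 of log2(FPKM + 1) over the tested genes, with one point per library, coloured by population and marked with its replicate number. Component 1 (55.4% of variance) separates dermal stem cells and dermal papilla on the left from the libraries labelled dermal sheath and interfollicular dermis on the right.

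Of the 2 reporter genes, Acta2 set the dermal stem cells apart. Acta2, which encodes smooth muscle actin (chromosome 19, 34240336 to 34255585), averaged 872 ± 26 FPKM in dermal stem cells, 49.3 ± 23.1 in dermal sheath, 45.4 ± 35.8 in dermal papilla and 8.7 ± 2.6 in interfollicular dermis. It was lower in dermal papilla than in dermal stem cells (fold change -4.50, SE 0.45, adjusted p = 0.000124) and lower in dermal sheath than in dermal stem cells (-4.21, adjusted p = 1.97e-05), and it was higher in dermal sheath than in interfollicular dermis (2.32, adjusted p = 0.0182). Sox2, a transcription factor of the dermal papilla (chromosome 3, 34649995 to 34652461), was read at 0.882, 2.66 and 7.17 FPKM in the dermal papilla libraries and averaged 1.14 ± 0.0292 in dermal stem cells, 0.153 ± 0.129 in dermal sheath and 0.241 ± 0.115 in interfollicular dermis. It was higher in dermal papilla than in dermal sheath (1.74, adjusted p = 0.00418) and interfollicular dermis (1.63, adjusted p = 0.00761). Its difference between dermal papilla and dermal stem cells did not pass (0.84, adjusted p = 0.227).

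Mesenchymal transcripts were abundant in dermal stem cells and dermal papilla and scarce in the other 6 libraries. Col1a1, the main fibrillar collagen chain of dermis, averaged 2760 ± 425 FPKM in dermal stem cells and 5510 ± 2250 in dermal papilla, but 235 ± 134 in the libraries labelled dermal sheath and 197 ± 200 in those labelled interfollicular dermis. The intermediate filament gene Vim averaged 1700, 878, 117 and 138 in the same order, and Pdgfra, a receptor of dermal fibroblasts, 56.2, 34.9, 3.23 and 3.5. Some epithelial genes ran the other way: Trp63, which maintains basal keratinocytes, averaged 15.5, 16.1, 121 and 89, and the basal keratin gene Krt5 118, 140, 395 and 378. Others did not: Krt10, a keratin of differentiated epidermis, averaged 361, 1530, 53.4 and 167. The keratinocyte list summed highest in dermal papilla replicates 1 and 2 (7194 and 7488 FPKM). The proliferation marker Mki67 averaged 7.32 and 4.62 against 100 and 61.7. Summed over the list of fibrillar and fibril-associated collagens, the lowest library of dermal stem cells and dermal papilla had 7106 FPKM and the highest of the other 6 had 1117. Which cells the libraries labelled dermal sheath and interfollicular dermis hold rests on the labels alone, and the names are used here in that sense.

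**Figure D2:**
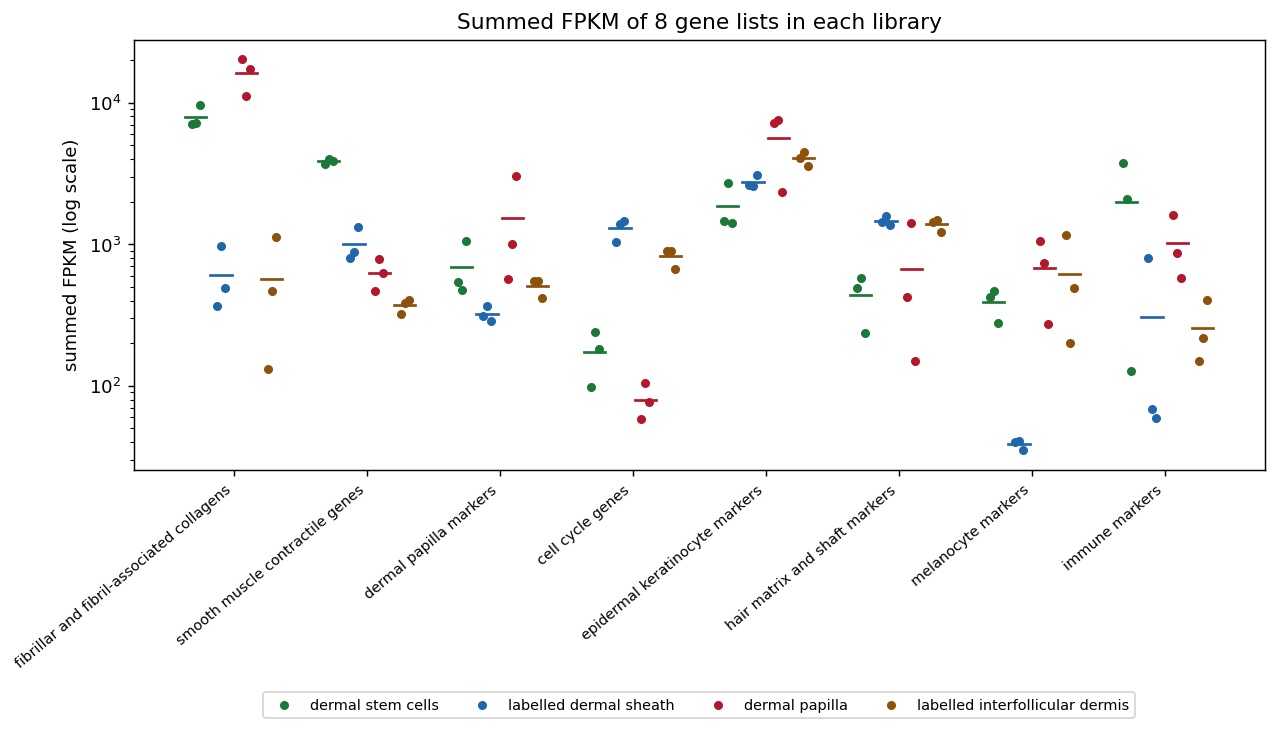
Summed FPKM (log axis) of the tested members of 8 gene lists in each of the 12 libraries, with points for libraries, coloured by population, and horizontal lines for the mean of 3. Every dermal stem cell and dermal papilla library lies at or above 7106 FPKM for collagens and every other library at or below 1117.

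The comparison of dermal papilla with dermal stem cells asks what distinguishes the signalling centre of the follicle from the mesenchymal stem cells beside it. Of 22 smooth muscle contractile genes 19 were higher in dermal stem cells. Of 11 secreted Wnt antagonist genes 6 were higher in dermal papilla and 1 lower. With an estimated correlation neither list passed (camera adjusted p = 0.0826 for both). Of 12774 genes, 1110 differed, 295 higher and 815 lower in dermal papilla, and 278 and 683 of them by at least 2-fold. The largest differences with values above 0 in every library were in Lrrc15, a membrane protein gene of activated fibroblasts, and Adamts18, a secreted metalloproteinase gene. Lrrc15 (chromosome 16, 30269302 to 30283254) averaged 9.2 ± 5.8 FPKM in dermal papilla and 305 ± 135 in dermal stem cells (fold change -4.96, SE 0.39, adjusted p = 3.7e-05), and Adamts18 (chromosome 8, 113697123 to 113849343) 0.709 ± 0.389 and 45.9 ± 10.4 (-4.78, SE 0.29, adjusted p = 2.6e-06).

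Smooth muscle contractile genes were among those higher in dermal stem cells. Actg2, the gamma smooth muscle actin gene, averaged 13.9 ± 3.81 FPKM in dermal papilla and 236 ± 6.83 in dermal stem cells (-4.02), and the actin-binding Tagln 38.6 ± 19.4 and 577 ± 27.2 (-3.97). Tnnt1, a troponin T of slow muscle, fell by 4.45 on the log2 scale, and Casq2, a calcium store protein of muscle, fell by 4.33. Of the 22 smooth muscle contractile genes tested, 19 were lower in dermal papilla (20 adjusted over the list alone), among them the tropomyosin gene Tpm2 (-3.27) and the myosin light chain gene Myl9 (-3.15). The list passed with camera (adjusted p = 5.68e-16, and adjusted p = 0.0826 with an estimated correlation). Of 13 sheath marker genes 7 were lower (8 adjusted over the list alone), including Col11a1 (-3.56), the proteoglycan gene Acan (-3.43), the adhesion gene Mcam (-2.91) and Col12a1 (-2.81). The list's camera adjusted p was 1.21e-05 (adjusted p = 0.171 with an estimated correlation).

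Other genes higher in dermal stem cells included Stmn2, a microtubule regulator of neurons (2.24 ± 1.15 against 76.1 ± 57 FPKM, -4.37), and the growth factor binding protein genes Igfbp2 (7.61 ± 5.17 against 134 ± 54, -4.05) and Igfbp4 (88.5 ± 32 against 1030 ± 221, -3.57). The matricellular gene Ctgf, a TGF-beta target, averaged 39.6 ± 16.1 and 310 ± 53.1 (-2.99), and Mgp, an inhibitor of calcification, 190 ± 45.5 and 1480 ± 524 (-2.93). Gli1 (-2.08) and Gli2 (-1.97), transcription factors of hedgehog signalling, and Heyl (-1.75), a Notch effector, were also higher in dermal stem cells. Among 23 axon guidance ligand genes 8 were lower in dermal papilla and 1 higher (12 and 1 adjusted over the list alone), with Slit2 (-2.66) and Ntn1 (-2.57) foremost (camera adjusted p = 0.0335, adjusted p = 0.356 with an estimated correlation). The call ended without dermal papilla replicate 4 (0.113), with the replicate block (0.0878) and with a pseudocount of 0.1 (0.0647). Hspb2, a small heat shock protein gene (37.6, 42.2 and 52 FPKM), and Spcs1, a signal peptidase subunit gene (20.7, 22.1 and 28.4), were listed at 0 in all 9 other libraries. Rnf214 was listed at 0 in the 3 dermal stem cell libraries and at 6.37, 8.04 and 10.1 in dermal papilla.

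Secreted Wnt antagonists were among the genes higher in dermal papilla. Sfrp2 (chromosome 3, 83765750 to 83774314), which binds Wnt ligands, averaged 174 ± 18.5 FPKM in dermal papilla and 16.8 ± 5.94 in dermal stem cells (3.34, SE 0.37, adjusted p = 0.00022), and its relative Sfrp4 93.1 ± 27.9 and 8.02 ± 3.82 (3.41, SE 0.37, adjusted p = 0.00022). Of 11 secreted Wnt antagonist genes 6 were higher and 1 lower (7 and 1 adjusted over the list alone), including Sfrp1 (2.21) and Notum (2.18). Camera gave the list adjusted p = 7.7e-08 (adjusted p = 0.0826 with an estimated correlation). Rspo3 (chromosome 10, 29453106 to 29535867), an enhancer of Wnt signalling, averaged 98 ± 87.9 and 6.39 ± 1.33 (3.37, adjusted p = 0.0022). Of 14 Wnt target genes 3 were higher, including Tnfrsf19 (1.47), and with adjustment over the list alone 5 were higher and 1 lower. Camera gave the list adjusted p = 0.000104 (adjusted p = 0.176 with an estimated correlation). Of 21 BMP pathway genes 5 were higher in dermal papilla (5 adjusted over the list alone), including the antagonist genes Chrdl1 (2.12) and Fst (1.69) and the ligand gene Bmp7 (1.85). The list test gave adjusted p = 6.75e-05 with camera and adjusted p = 0.124 with an estimated correlation. Spock3, a matrix proteoglycan gene, averaged 9.52 ± 5.65 and 0.2 ± 0.203 (2.97).

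Crabp1, a retinoic acid binding protein gene of dermal papilla (chromosome 9, 54764748 to 54773110), averaged 311 ± 288 FPKM in dermal papilla and 30 ± 9.17 in dermal stem cells (2.92, adjusted p = 0.019), and its call ended without dermal stem cells replicate 1 (adjusted p = 0.0698) or 2. The steroid enzyme gene Akr1c18 (3.54) and the defensin gene Defb6 (2.96) also passed. The call of Akr1c18 ended without dermal stem cells replicate 1 (adjusted p = 0.0657) or dermal papilla replicate 1, and that of Defb6 without dermal stem cells replicate 4 (adjusted p = 0.0731) or 1 or dermal papilla replicate 2. Of 27 papilla marker genes 4 were higher and 3 lower in dermal papilla (5 and 5 adjusted over the list alone), with camera adjusted p = 0.00318, adjusted p = 0.606 with an estimated correlation, and 0.39 without dermal papilla replicate 4. Of 21 interfollicular fibroblast marker genes 5 were higher, including Dpp4 (2.52), and 2 lower (8 and 2 adjusted over the list alone). For this list, camera gave adjusted p = 1.11e-05, and adjusted p = 0.159 with an estimated correlation.

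Some markers of other cell types also differed in this comparison. Of 14 melanocyte genes 6 were higher and 1 lower in dermal papilla (12 and 1 adjusted over the list alone). With camera the list had adjusted p = 1.72e-10, and adjusted p = 0.196 with an estimated correlation. The pigment enzyme gene Dct averaged 202 ± 111 and 18.5 ± 12.9 FPKM (3.51) and the melanosome gene Mlana 108 ± 47 and 13.1 ± 10.1 (3.21), while Ednrb was lower (-2.56). Of 20 keratinocyte genes 4 were higher (9 adjusted over the list alone; camera adjusted p = 1.46e-09, adjusted p = 0.176 with an estimated correlation), and of 13 Schwann cell genes 4, including Cdh19 (2.66), were higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 2.18e-05, adjusted p = 0.14 with an estimated correlation). Of 36 cell cycle genes 6 were lower in dermal papilla (10 adjusted over the list alone). The list's camera adjusted p was 8e-04 (adjusted p = 0.596 with an estimated correlation). For hair matrix and shaft genes, of which 1 of 19 was higher, camera gave adjusted p = 0.0363 and adjusted p = 0.684 with an estimated correlation. The hair matrix call ended with the replicate block (0.0584), with quantile normalization (0.147), without dermal stem cells replicate 4 (0.217) and, in the other direction, without dermal papilla replicate 2 (0.762). The lists of hedgehog, Notch, FGF, TGF-beta, IGF and PDGF, collagen, basement membrane, matrix enzyme, Wnt ligand, Hox, interferon, immediate early, endothelial, pericyte, immune, skeletal muscle and adipocyte genes did not pass (camera adjusted p from 0.133 for immune to 0.885 for collagen genes).

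With the replicate number as a block in these 6 libraries 658 genes passed (208 higher, 450 lower), without the block in the same 6 libraries 512, and without dermal stem cells replicate 1, 2 or 4 in turn 515, 625 and 709. Median-of-ratios scaling moved the median of all genes by 0.18 and gave 460 higher and 513 lower among 973, and without dermal stem cells replicates 1 and 2 together (chosen after seeing the data) 182 passed and the calls of Rspo3, Rspo2, Sfrp1, Notum, Bmp7, Fst and Ednrb ended, as did those of Dct, Mlana and Dpp4 without dermal papilla replicates 1 and 2 together.

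**Figure D3:**
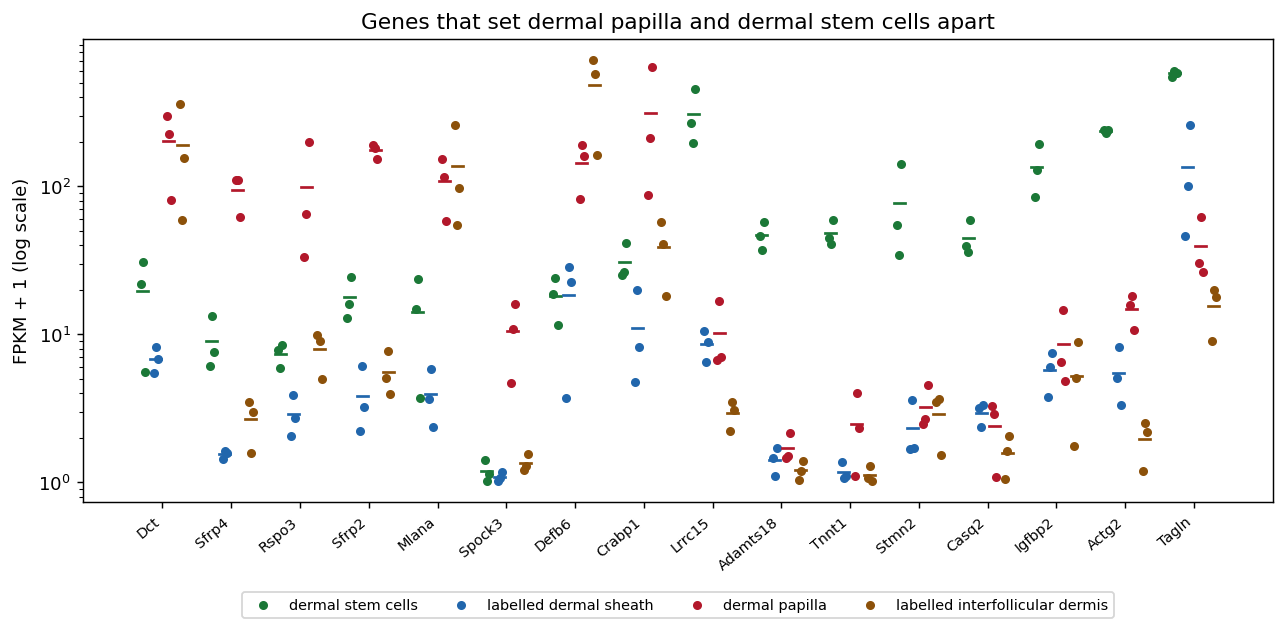
FPKM + 1 (log axis) of 16 of the most different genes between dermal papilla and dermal stem cells in all 12 libraries, with points for libraries and horizontal lines for the mean of 3. Lrrc15, Adamts18, Tnnt1, Stmn2, Casq2, Igfbp2, Actg2 and Tagln are highest in dermal stem cells, and Sfrp2, Sfrp4, Rspo3 and Spock3 in dermal papilla.

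The comparison of dermal sheath with dermal stem cells would show how the stem cells differ from their sheath progeny only if the labels hold. The libraries labelled dermal sheath had little Pdgfra (3.23 FPKM) and held epithelial transcripts (Trp63 at 121 and Krt5 at 395). A difference in the kind of cell sorted therefore cannot be told apart from one between stem cells and progeny. The libraries labelled dermal sheath had more cell cycle transcripts, and fewer of most listed matrix, contractile and fibroblast genes, than dermal stem cells. With an estimated correlation camera passed 0 of the 31 lists in this comparison. In all, 5607 genes differed, 3105 higher and 2502 lower in dermal sheath. Every one of the 36 cell cycle genes tested was higher (36 adjusted over the list alone), among them Mki67 (100 ± 8.73 against 7.32 ± 3.33 FPKM, fold change 3.70, SE 0.32, adjusted p = 4.8e-06; chromosome 7, 135689784 to 135716450) and the DNA topoisomerase gene Top2a (110 ± 23.7 against 10.6 ± 6.05, 3.42). The list had camera adjusted p = 5.68e-16 and adjusted p = 0.176 with an estimated correlation.

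Most of the tested collagen, matrix enzyme and basement membrane genes were lower in dermal sheath. Mfap5, a microfibril gene (chromosome 6, 122513584 to 122529290), averaged 0.799 ± 0.832 FPKM in dermal sheath and 228 ± 36.3 in dermal stem cells (-7.07, SE 0.33, adjusted p = 6.6e-08). Col3a1 (chromosome 1, 45311538 to 45349706) averaged 114 ± 92.4 and 1840 ± 173 (-4.30, SE 0.65, adjusted p = 0.00026), and 15 of 16 fibrillar and fibril-associated collagen genes were lower (16 adjusted over the list alone; camera adjusted p = 1.72e-10, adjusted p = 0.124 with an estimated correlation). The matricellular genes Sparc (240 ± 114 against 4020 ± 951, -4.13) and Postn (52.5 ± 15.3 against 1130 ± 495, -4.35) moved the same way. Of 24 matrix enzyme genes 17 were lower (18 adjusted over the list alone), including Adamts18 (-5.04), Mmp2 (-4.50) and Loxl1 (-4.08). Camera gave the list adjusted p = 2.22e-10 (adjusted p = 0.0826 with an estimated correlation). Of 18 basement membrane genes 11 were lower, including Nid2 (-4.43) and Nid1 (-4.16), and 2 higher. The list test gave adjusted p = 0.00314 with camera and adjusted p = 0.484 with an estimated correlation.

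Many of the genes listed as markers of mesenchymal cells were lower as well. Of 21 interfollicular fibroblast genes 17 were lower and 1 higher (17 and 1 adjusted over the list alone), including Clec3b (1.34 ± 0.163 against 125 ± 33.2 FPKM, -5.71), Dpt (-5.21) and Ly6a (-5.08). The list test gave adjusted p = 4.16e-10 with camera and adjusted p = 0.0826 with an estimated correlation. Dpep1, a membrane dipeptidase gene, averaged 3.21 ± 0.687 and 224 ± 58.9 (-5.72), and the phospholipid transfer gene Pltp 4.23 ± 3.89 and 224 ± 169 (-5.61). Of 22 smooth muscle genes 17 were lower (17 adjusted over the list alone), including Actg2 (-5.52) and the kinase gene Mylk (-4.07). For this list, camera gave adjusted p = 1.95e-08, and adjusted p = 0.124 with an estimated correlation. Of 13 dermal sheath marker genes 10 were lower in the libraries labelled dermal sheath and 1 higher (10 and 1 adjusted over the list alone). With camera the list had adjusted p = 5.69e-06, and adjusted p = 0.159 with an estimated correlation. Of 27 papilla marker genes 11 were lower and 2 higher (12 and 3 adjusted over the list alone), with camera adjusted p = 0.0126, adjusted p = 0.651 with an estimated correlation, and 0.0963 without dermal stem cells replicate 4.

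Growth factor lists fell in part. Of 16 TGF-beta and activin genes 13 were lower, including Fstl1 (-3.83) and Ctgf (-3.17), and of 16 IGF and PDGF genes 11 were lower, including Igfbp4 (-4.76) and Igf1 (-4.11). The camera adjusted p-values were 2.05e-06 and 1.5e-05, and with an estimated correlation the adjusted p-values were 0.11 and 0.0826. Of 11 secreted Wnt antagonist genes 6 were lower, including Dkk3 (-2.90). The list's camera adjusted p was 0.00209 (adjusted p = 0.23 with an estimated correlation). Of 17 interferon-stimulated genes 15 were lower. For this list, camera gave adjusted p = 4.87e-06, and adjusted p = 0.314 with an estimated correlation. The interferon list summed to 291, 196 and 96 FPKM in dermal stem cells replicates 1, 2 and 4, where the immune list summed to 3740, 2077 and 127. Of 23 axon guidance genes 12 were lower, including Sema3d (-4.60) and Slit2 (-4.30), and 5 higher (12 and 6 adjusted over the list alone; camera adjusted p = 0.0271, adjusted p = 0.328 with an estimated correlation, 0.0531 with the replicate block). Of 7 adipocyte genes 3 were lower, including the lipase gene Lpl (-4.76). Camera gave the list adjusted p = 0.0223 (adjusted p = 0.151 with an estimated correlation).

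Part of the hair matrix and shaft list was higher in dermal sheath. Trp63 rose by 2.93 on the log2 scale (adjusted p = 4.1e-05), and 10 of 19 hair matrix and shaft genes were higher (11 adjusted over the list alone), including the transcription factor genes Dlx3 (3.37), Lhx2 (3.33) and Msx2 (3.12) and the inner root sheath keratin gene Krt28 (173 ± 23.6 against 19.1 ± 14 FPKM, 3.36). That list had camera adjusted p = 0.0308 and adjusted p = 0.67 with an estimated correlation, and adjusted p = 0.0734 without dermal stem cells replicate 4 and 0.0595 without dermal sheath replicate 4. Of 20 keratinocyte genes 10 were higher and 4 lower (12 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0962). Dlx2, a homeobox gene, averaged 73.6 ± 36.6 and 5.69 ± 5.43 (3.65). The Notch genes Jag2 (2.62) and Notch1 (2.51) and the ligand gene Wnt4 (2.58) were higher, while the Notch and Wnt ligand lists did not pass. Of 26 Hox genes 12 were higher, including Hoxb8 (3.38) and Hoxb6 (3.09), and 7 lower, including Hoxc10 (-2.60), and that list did not pass (camera adjusted p = 0.522). The Wnt target, R-spondin, hedgehog, FGF, BMP, immediate early, melanocyte, Schwann cell and skeletal muscle lists did not pass either (camera adjusted p from 0.0667 for immediate early to 0.812 for FGF genes).

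Macrophage genes were among the largest differences and came from part of the dermal stem cell libraries. The complement gene C1qa was read at 628, 235 and 13 FPKM in dermal stem cells replicates 1, 2 and 4 and averaged 1.79 ± 2.55 in dermal sheath (-5.89, SE 1.11, adjusted p = 0.0012), and the chemokine gene Ccl8 differed by -6.22 (SE 1.43, adjusted p = 0.0039). Of 21 immune genes 8 were lower in dermal sheath (7 adjusted over the list alone). With camera the list had adjusted p = 0.00209, and adjusted p = 0.622 with an estimated correlation. Of 16 endothelial genes 3 were lower, and of 14 pericyte genes 5 were lower and 1 higher, with camera adjusted p-values of 0.0335 and 0.0363, and with an estimated correlation the adjusted p-values were 0.722 and 0.569. Polr2b, Pold2, Pigf, Arg2 and Cdc20 were listed at 0 in all dermal stem cell and dermal papilla libraries and above 0 in the others. Polr2b stood at 34.7, 38.4 and 40.4 FPKM in dermal sheath. Kdelr3 was listed at 0 in dermal sheath and interfollicular dermis and at 40.3, 48.2 and 69.5 in dermal stem cells. These values of 0 followed the same split of populations as the first principal component, and what gave them was not tested.

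Without dermal stem cells replicates 1 and 2 together (chosen after seeing the data) 2620 genes passed, and the calls of C1qa, Ccl8 and Lgr4 ended. Median-of-ratios scaling moved the median of all genes by -0.17 and gave 2267 higher and 2828 lower among 5095, the endothelial list ended without dermal sheath replicate 5 (adjusted p = 0.144) or dermal stem cells replicate 1 (0.11) or 2 (0.0622), and the pericyte list without dermal sheath replicate 5 (0.0981) or 4 (0.0605) or dermal stem cells replicate 2 (0.05). With the replicate block neither of these lists passed (camera adjusted p = 0.341 for endothelial and 0.225 for pericyte genes).

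The comparison of dermal papilla with dermal sheath asks what distinguishes the papilla from the tissue continuous with it, as far as the sheath label holds. Dermal papilla had more transcripts of most collagens and fibroblast markers and of secreted Wnt antagonists, and the libraries labelled dermal sheath had more of cell cycle genes. None of the 31 lists passed here when camera used an estimated correlation. In all, 6365 genes differed, 2094 higher and 4271 lower in dermal papilla. Clec3b, a secreted lectin gene, averaged 276 ± 82.7 FPKM in dermal papilla and 1.34 ± 0.163 in dermal sheath (fold change 6.84, SE 0.4, adjusted p = 4.2e-07), the extracellular peroxidase gene Gpx3 603 ± 178 and 8.43 ± 5.64 (6.22), the matrix gene Dpt 520 ± 124 and 6.7 ± 4.03 (6.18) and the pentraxin gene Ptx3 276 ± 69.1 and 3.21 ± 1.02 (6.04). The list of interfollicular fibroblast markers, which holds Clec3b, Gpx3 and Dpt, had 18 of 21 genes higher (18 adjusted over the list alone; camera adjusted p = 5.68e-15, adjusted p = 0.0826 with an estimated correlation).

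Most collagen and matrix enzyme genes, and 9 of 18 basement membrane genes, were higher in dermal papilla. Col3a1 averaged 5170 ± 996 FPKM against 114 ± 92.4 (5.78, SE 0.65, adjusted p = 2.7e-05), and 13 of 16 collagen genes were higher (13 adjusted over the list alone), including Col1a2 (4.93) and Col1a1 (4.63). The list test gave adjusted p = 9.25e-10 with camera and adjusted p = 0.124 with an estimated correlation. Of 24 matrix enzyme genes 17 were higher, including Mmp2 (4.90) and the crosslinking enzyme gene Lox (4.76), and 1 lower. The list's camera adjusted p was 2.22e-10 (adjusted p = 0.0826 with an estimated correlation). Of 18 basement membrane genes 9 were higher, including Sparc (4.80), and 4 lower, including Lama5 (-3.33). Camera gave the list adjusted p = 0.00233 (adjusted p = 0.464 with an estimated correlation). Mfap5 (5.98) and the chemoattractant gene Rarres2 (5.95) were also higher.

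Of 27 papilla marker genes 15 were higher, including Rspo3 (4.75), Crabp1 (4.62), the growth factor gene Fgf7 (154 ± 157 against 7.54 ± 8.34 FPKM, 4.13) and Inhba (3.62), and 4 lower. For this list, camera gave adjusted p = 0.000205, and adjusted p = 0.552 with an estimated correlation. All 11 secreted Wnt antagonist genes were higher, including Sfrp4 (5.88), Sfrp2 (5.63) and Wif1 (3.30). With camera the list had adjusted p = 3.43e-08, and adjusted p = 0.0826 with an estimated correlation. Of 16 IGF and PDGF genes 10 were higher, including Igfbp6 (5.02) and Igf1 (4.74), and of 16 TGF-beta and activin genes 10 were higher and 1 lower. Their camera adjusted p-values were 1.98e-05 and 1.5e-05, and with an estimated correlation the adjusted p-values were 0.0826 and 0.124. Of 21 BMP pathway genes 9 were higher, including Chrdl1 (3.92), and 5 lower, including Id1 (-2.67). The list test gave adjusted p = 0.0111 with camera and adjusted p = 0.306 with an estimated correlation. Of 13 sheath marker genes 5 were higher in dermal papilla and 2 lower (camera adjusted p = 0.0362, adjusted p = 0.549 with an estimated correlation, 0.0595 without dermal papilla replicate 2 and 0.0985 without replicate 4).

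All 36 cell cycle genes were lower in dermal papilla, including Mki67 (-4.22), the replication helicase gene Mcm5 (-4.12) and Rrm2, a subunit of ribonucleotide reductase (-4.38). The list's camera adjusted p was 5.68e-16 (adjusted p = 0.176 with an estimated correlation). Dlx2 averaged 0.85 ± 1.23 FPKM against 73.6 ± 36.6 (-5.41), the zinc transporter gene Slc39a10 4.01 ± 0.823 against 153 ± 43.5 (-4.91) and Lhx2 2.16 ± 1.16 against 90.4 ± 42.9 (-4.81). In the hedgehog list 7 of 12 genes were lower, including the receptor gene Ptch1 (-2.31), which is also a pathway target, and Gli1 (-2.40), and 3 were higher, including the antagonist gene Hhip (2.75). That list did not pass (camera adjusted p = 0.488). Of 16 Notch genes 8 were lower, including Jag2 (-3.59) and Notch1 (-2.52), and 1 higher (9 and 1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.207). Rfc4 was listed at 0 in dermal papilla and at 38.3, 43.8 and 50.5 FPKM in dermal sheath.

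Genes of other cells also differed. Of 14 melanocyte genes 12 were higher in dermal papilla and 1 lower (13 and 1 adjusted over the list alone), including Mlana (4.77) and Dct (4.72), and Pmel was listed at 0 in dermal sheath and at 30.9, 133 and 199 FPKM in dermal papilla. For this list, camera gave adjusted p = 8.95e-07, and adjusted p = 0.328 with an estimated correlation. The keratins of differentiated epidermis Krt1 (5.71) and Krt10 (5.06) were higher and Trp63 (-2.92) lower, 4 of 20 keratinocyte genes being higher and 4 lower (camera adjusted p = 0.235). Of 21 immune genes 11 and of 17 interferon-stimulated genes 9 were higher, and of 13 Schwann cell genes 8 were higher and 1 lower, with camera adjusted p-values of 0.000164, 3.22e-05 and 0.000181, and with an estimated correlation the adjusted p-values were 0.569, 0.368 and 0.176. Of 7 adipocyte genes 4 were higher. With camera the list had adjusted p = 0.00318, and adjusted p = 0.0826 with an estimated correlation. The endothelial, pericyte and skeletal muscle lists passed with camera adjusted p-values of 0.00868, 0.0384 and 0.0498, and with an estimated correlation the adjusted p-values were 0.651, 0.569 and 0.457. Each of these 3 lists failed the threshold without dermal papilla replicate 2 (adjusted p = 0.0658, 0.0938 and 0.0809) and with the replicate block (0.141, 0.243 and 0.0813). The pericyte list also failed without dermal sheath replicate 4 (0.0537) or 5 (0.111), and the skeletal muscle list without dermal stem cells replicate 1 (0.0501), any dermal sheath library (0.0565 to 0.0657) or dermal papilla replicate 1 (0.145). The Wnt target, Wnt ligand, FGF, Hox, axon guidance, immediate early, hair matrix and smooth muscle lists did not pass (camera adjusted p from 0.256 for immediate early to 0.887 for Hox genes). Median-of-ratios scaling moved the median of all genes by 0.36 and gave 2871 higher and 2612 lower among 5483.

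Mean transcripts of the R-spondin ligands were highest in dermal papilla, and those of the LGR receptors in the libraries labelled dermal sheath. Those libraries also held epithelial transcripts (Trp63 at 121 and Krt5 at 395 FPKM), and which cells in them carry the receptor transcripts was not tested. The ligands amplify Wnt signalling through LGR receptors and the ubiquitin ligases ZNRF3 and RNF43. All 4 ligand genes were higher in dermal papilla than in dermal sheath: Rspo3 (98 ± 87.9 against 1.9 ± 0.934 FPKM, fold change 4.75), Rspo4 (44 ± 36.2 against 2.02 ± 2.24, 3.89; chromosome 2, 151842647 to 151874668), Rspo1 (57.1 ± 50.4 against 3.2 ± 1.82, 3.54; chromosome 4, 124986401 to 125009102) and Rspo2 (21.2 ± 19.1 against 0.903 ± 0.455, 3.22; chromosome 15, 43020788 to 43171594). Each ligand was highest in dermal papilla replicate 4, with Rspo3 at 198 FPKM there and at 32.4 and 63.8 in replicates 1 and 2. The receptors ran the other way, with Lgr5 (chromosome 10, 115450314 to 115587780) at 2.2 ± 0.28 in dermal papilla and 23.2 ± 8.97 in dermal sheath (-2.85), Lgr6 lower by -3.28 and Lgr4 by -1.92, and Rnf43 (-2.38) and Znrf3 (-1.73) were also lower. Because the 9 genes moved both ways, the list's median was -1.73 and its mean 0.36, and camera gave adjusted p = 0.912 upward where fry gave adjusted p = 0.046 downward.

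Against dermal stem cells, dermal papilla had more Rspo3 (3.37), Rspo2 (2.51, adjusted p = 0.0067) and Rspo4 (2.49, adjusted p = 0.026), and less Lgr6 (-1.31, adjusted p = 0.03). Leaving out one library raised the adjusted p to 0.0977 for Rspo4 (without dermal stem cells replicate 2, and past the threshold also without 1 or 4 or dermal papilla replicate 4) and to 0.105 for Lgr6 (without dermal stem cells replicate 4, and also without 1 or 2 or dermal papilla replicate 1 or 4). Rspo1 (1.29, adjusted p = 0.18), Lgr4 (-0.58), Lgr5 (-0.62, adjusted p = 0.35), Znrf3 (0.12) and Rnf43 (-0.12) did not pass. The list had camera adjusted p = 0.0202 and adjusted p = 0.314 with an estimated correlation, with 3 genes higher and 1 lower (3 and 1 adjusted over the list alone), and adjusted p = 0.0926 without dermal stem cells replicate 1 and 0.0614 without dermal papilla replicate 4. Dermal sheath had more Lgr5 (2.23, adjusted p = 7e-04), Lgr6 (1.96), Lgr4 (1.35), Rnf43 (2.26) and Znrf3 (1.85) than dermal stem cells and less Rspo1 (-2.25, adjusted p = 0.0068), and its list, with 5 genes higher and 2 lower (5 and 3 adjusted over the list alone), did not pass (camera adjusted p = 0.294). Rspo3 was also lower there (-1.38, adjusted p = 0.046), a call that 8 of the 12 fits with one library left out ended (adjusted p up to 0.136).

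**Figure D4:**
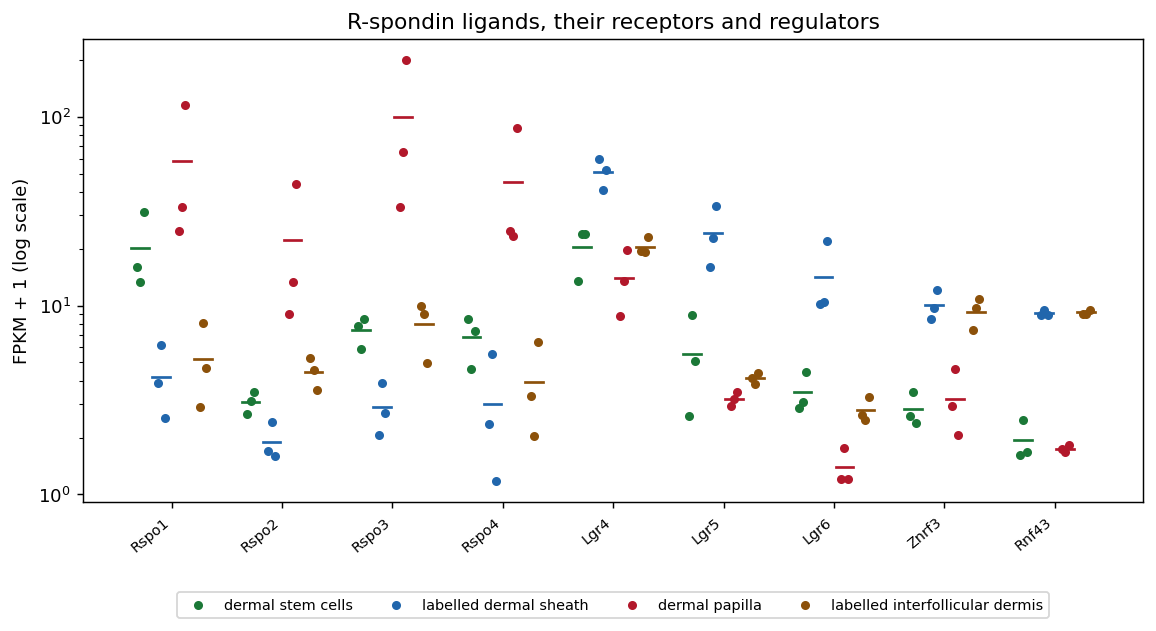
FPKM + 1 (log axis) of the 4 R-spondin genes, 3 LGR receptor genes and the ubiquitin ligase genes Znrf3 and Rnf43 in the 12 libraries, with points for libraries, coloured by population, and horizontal lines for the mean of 3. The mean of each ligand is highest in dermal papilla, and those of Lgr5 and Lgr6 in the libraries labelled dermal sheath.

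The comparison of the follicle populations with interfollicular dermis asks what marks the mesenchyme of the follicle, as far as the labels hold. Averaged over dermal stem cells, dermal sheath and dermal papilla, with equal weight, follicle mesenchyme had more transcripts of the matrix and contractile lists than the libraries labelled interfollicular dermis, which had more than that mean of cell cycle genes and of some hair keratin and globin genes. The collagen excess came from dermal stem cells and dermal papilla and not from dermal sheath. Camera with an estimated correlation passed 0 of the 31 lists here. In all, 3384 genes differed, 1499 higher and 1885 lower in the follicle. The follicle mean joins unlike populations, so its SD over 9 libraries is large: Itgbl1, a gene for an integrin-like secreted protein, averaged 67.6 ± 66.6 FPKM against 1.41 ± 1.46 (fold change 4.01, SE 0.29, adjusted p = 6.5e-06), the proteoglycan gene Bgn 918 ± 928 against 46.1 ± 7.98 (3.58), Actg2 84.7 ± 113 against 0.973 ± 0.697 (3.80) and the matrix gene Efemp1 75.8 ± 40.7 against 6.55 ± 1.15 (3.07, SE 0.18, adjusted p = 1.9e-06). For these named genes every one of the 9 follicle libraries lay above the 3 others, because the rule for named genes requires it.

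Collagen genes were higher in the follicle mean in 15 of 16 cases (15 adjusted over the list alone; camera adjusted p = 3.97e-14, adjusted p = 0.0826 with an estimated correlation), including Col1a1 (3.64) and Col6a1 (3.22). This excess came from dermal stem cells and dermal papilla, where the collagen list summed to 7106 to 20292 FPKM, against 367, 976 and 487 in dermal sheath and 131, 469 and 1117 in interfollicular dermis. Of 24 matrix enzyme genes 18 were higher (20 adjusted over the list alone; camera adjusted p = 3.01e-14, adjusted p = 0.0826 with an estimated correlation), including Lox (3.17), and of 22 smooth muscle genes 16 (19 adjusted over the list alone; camera adjusted p = 2.56e-12, adjusted p = 0.0826 with an estimated correlation), including Tagln (3.15) and Myl9 (3.06). Of 21 interfollicular fibroblast markers 18 were higher in the follicle mean rather than in interfollicular dermis (19 adjusted over the list alone; camera adjusted p = 5.68e-16, adjusted p = 0.0826 with an estimated correlation), including Dpt (3.89), Ly6a (3.23) and Lum (3.15). That list summed to 4108 to 7439 FPKM in dermal stem cells and dermal papilla, and dermal sheath (740, 1157 and 829) shared little of the excess over interfollicular dermis (724, 879 and 604). Of 18 basement membrane genes 11 were higher, including Sparc (3.23), and 1 lower (14 and 2 adjusted over the list alone; camera adjusted p = 4.18e-07, adjusted p = 0.196 with an estimated correlation). The basement membrane sums of dermal sheath (510, 591 and 496) lay within those of interfollicular dermis (212, 347 and 647). Of 13 sheath marker genes 10 were higher, including Mfap5 (3.94) and Postn (3.80), and 1 lower. The list's camera adjusted p was 3.26e-07 (adjusted p = 0.124 with an estimated correlation). Of 16 IGF and PDGF genes 11 were higher, including Igfbp7 (2.58), and 1 lower, and of 16 TGF-beta and activin genes 10 were higher (11 adjusted over the list alone), including Fstl1 (2.94), with camera adjusted p-values of 3.26e-07 and 1.59e-07 and, for both, adjusted p = 0.0826 with an estimated correlation.

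Several hair epithelial genes were higher in interfollicular dermis than in the follicle mean. Shh, the hedgehog ligand of hair matrix epithelium, averaged 65.1 ± 21.5 FPKM there and 1.25 ± 0.871 in the follicle populations (-4.90, SE 0.25, adjusted p = 6.1e-07), and the hair shaft keratin gene Krt35 (chromosome 11, 100092192 to 100096224) 308 ± 55.4 and 13.3 ± 9.72 (-4.64, SE 0.4, adjusted p = 1.3e-05). Krt79 (-3.79), a keratin of the upper follicle, and Hoxc13 (-3.29), a regulator of hair keratins, followed. Of 19 hair matrix and shaft genes 8 were lower in the follicle (10 adjusted over the list alone; camera adjusted p = 0.00208, adjusted p = 0.569 with an estimated correlation), and of 20 keratinocyte genes 8 were lower and 1 higher (camera adjusted p = 0.00581, adjusted p = 0.569 with an estimated correlation, 0.252 with the replicate block). Cell cycle genes were lower in 31 of 36 cases (35 adjusted over the list alone; camera adjusted p = 6.83e-13, adjusted p = 0.233 with an estimated correlation), including Mki67 (-1.94) and Ccna2 (-1.94). This lower mean came from dermal stem cells and dermal papilla: the cell cycle list summed to 98, 240 and 181 and to 58, 105 and 77 FPKM there, and to 1042, 1379 and 1458 in dermal sheath against 896, 900 and 670 in interfollicular dermis. The hair matrix list likewise summed to 1442, 1576 and 1370 in dermal sheath against 1436, 1485 and 1221 in interfollicular dermis. Of 14 Wnt target genes 6 were lower, including Tnfrsf19 (-2.84) and Lef1 (-2.64), and 1 higher (8 and 2 adjusted over the list alone; camera adjusted p = 0.0284, adjusted p = 0.457 with an estimated correlation). The ligand genes Wnt10b (-2.91) and Wnt10a (-2.03) were lower, and the Wnt ligand list, with 6 genes lower and 3 higher (7 and 4 adjusted over the list alone), did not pass (camera adjusted p = 0.296). The globin genes Hbb-bs (1800 ± 1410 against 94.7 ± 131, -5.15, adjusted p = 0.0034) and Hbb-bt (-5.06) and the haem synthesis gene Alas2 (-3.76) were higher in interfollicular dermis, and 9 of 14 melanocyte genes, including Mlana (-2.80), were lower in the follicle and 1 higher (10 and 1 adjusted over the list alone). Camera gave the list adjusted p = 0.00294 (adjusted p = 0.581 with an estimated correlation). Its sums were 1155, 201 and 494 FPKM in interfollicular dermis and 1046, 735 and 272 in dermal papilla, against 421, 468 and 278 in dermal stem cells and 40, 41 and 35 in dermal sheath.

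Among the remaining lists, axon guidance genes were higher in the follicle in 9 of 23 cases, including Slit3 (2.51), and lower in 2 (9 and 3 adjusted over the list alone). The list test gave adjusted p = 0.0104 with camera and adjusted p = 0.269 with an estimated correlation. Pericyte genes were higher in 6 of 14 cases, including Mcam (1.64), and interferon-stimulated genes in 6 of 17 (8 adjusted over the list alone), including Usp18 (1.39), with camera adjusted p-values of 0.00045 and 0.000265 and, with an estimated correlation, adjusted p-values of 0.314 and 0.457. The interferon list summed to 291, 196 and 96 FPKM in dermal stem cells and 132, 176 and 68 in dermal papilla. Dermal sheath (40, 34 and 24) did not share this excess over interfollicular dermis (32, 34 and 61). Immediate early genes were higher in 9 of 21 cases, including Socs3 (1.63), and lower in 1 (camera adjusted p = 0.00233, adjusted p = 0.464 with an estimated correlation, 0.179 with quantile normalization). Of 11 secreted Wnt antagonist genes 5 were higher, including Sfrp4 (2.06), and with adjustment over the list alone 1 was lower. Of 16 FGF genes 6 were higher and 1 lower (6 and 2 adjusted over the list alone). These lists passed with camera adjusted p-values of 0.0052 and 0.0196 and, with an estimated correlation, adjusted p-values of 0.285 and 0.314; with the replicate block neither passed (0.106 and 0.0887). Of 7 adipocyte genes 2 were higher (camera adjusted p = 0.045, adjusted p = 0.184 with an estimated correlation, and 0.0533 with a pseudocount of 0.1). That call also ended without dermal sheath replicate 4, dermal papilla replicate 2 or 4, or interfollicular dermis replicate 1 or 2 (adjusted p = 0.0529 to 0.0582). The papilla marker, Notch, hedgehog, BMP, Hox, R-spondin, endothelial, immune, Schwann cell and skeletal muscle lists did not pass (camera adjusted p from 0.0503 for immune to 0.581 for endothelial genes).

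Compared one by one with interfollicular dermis, dermal stem cells differed in 4800 genes, dermal papilla in 5400 and dermal sheath in 289, and the follicle mean of dermal stem cells and dermal papilla only (chosen after seeing the data) in 5931. Without interfollicular dermis replicate 1 or 2 the follicle count was 1848 or 1751, and median-of-ratios scaling moved the median of all genes by 0.13 and gave 1788 higher and 1241 lower among 3029.

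Some genes were higher in a population than in each of the other 3. Dermal stem cells had 451 such genes, dermal papilla 173, interfollicular dermis 75 and dermal sheath 68. In dermal stem cells the smallest of the 3 fold changes was 4.96 for Lrrc15, 4.78 for Adamts18, 4.45 for Tnnt1, 4.37 for Stmn2, 4.05 for Igfbp2 and 4.02 for Actg2. In dermal papilla it was 3.41 for Sfrp4, 3.34 for Sfrp2, 3.30 for Rspo3, 2.87 for the complement gene C7, 2.79 for Spock3 and 2.55 for Nrg2, a ligand of ERBB receptors. In dermal sheath it was 2.64 for Cntfr, a receptor for ciliary neurotrophic factor, 2.31 for Slc39a10, 2.23 for Lgr5, 2.16 for the monocarboxylate transporter gene Slc16a7 and 1.96 for Lgr6, and with the replicate block Slc39a10, Lgr5 and Lgr6 no longer passed all 3. In interfollicular dermis it was 4.36 for Shh, 4.23 for Krt35, 3.40 for Alas2, 3.03 for Krt79 and 2.72 for the netrin receptor gene Unc5b. Leaving out one library gave 260 to 468 genes for dermal stem cells, 79 (without dermal stem cells replicate 1) to 293 (without dermal papilla replicate 4) for dermal papilla, 18 (without dermal sheath replicate 5) to 87 for dermal sheath and 32 (without interfollicular dermis replicate 1) to 79 for interfollicular dermis.

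With the preset correlation 71 of the 124 list tests passed. With an estimated correlation (median 0.222) camera passed 0 of them, with 33 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0826, and fry, which asks whether genes of a list move one way, passed 68. Fry ended 14 of the 71 camera calls, among them papilla markers (fry adjusted p = 0.729) and hair matrix genes (0.813) in dermal papilla against dermal stem cells. Of the lists that camera had not called, fry passed 10 in the same direction and 1 in the other. In 22 of the 124 tests the list's median, mean, scaled median or tests differed in sign, and 0 of these 22 passed with camera. The R-spondin list in dermal papilla against dermal sheath is one of them.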

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

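Fits without 2 libraries together, the filter to genes above 0 in every library and the follicle mean without dermal sheath were chosen after seeing the data. Under every other alternative run, including each fit that left out one library, the counts for the F test (6351 to 7502 with one library left out), dermal sheath against dermal stem cells (4196 to 6083) and dermal papilla against dermal sheath (5112 to 6467) stayed within 1.5 times their values. With one library left out, dermal papilla against dermal stem cells ranged from 515 to 1422 genes, follicle against interfollicular dermis from 1751 to 3703, dermal sheath against interfollicular dermis from 103 (without dermal sheath replicate 5) to 431, and genes specific to dermal stem cells from 260 to 468, to dermal sheath from 18 to 87, to dermal papilla from 79 to 293 and to interfollicular dermis from 32 to 79. A pseudocount of 0.1 gave 294, 45, 80 and 39 genes specific to dermal stem cells, dermal sheath, dermal papilla and interfollicular dermis, and a pseudocount of 5 gave 118 for dermal sheath. Requiring a mean of 5 FPKM, which tests fewer genes, gave 738 for dermal papilla against dermal stem cells and 287, 79 and 34 specific to dermal stem cells, dermal papilla and interfollicular dermis. Quantile normalization gave 267 specific to dermal papilla, and median-of-ratios scaling 274 for dermal papilla and 45 for dermal sheath. Array weights gave 706 for dermal sheath against interfollicular dermis and 220 specific to dermal sheath, and the replicate block 150, 32 and, for interfollicular dermis, 40. Dermal papilla against dermal stem cells gave 512 on its 6 libraries alone and 658 with the block there. Without dermal stem cells replicates 1 and 2 together, which leaves 1 library assumed to vary like the other groups, the counts were 182 for dermal papilla and 2620 for dermal sheath against dermal stem cells, 2005 for dermal stem cells and 162 for dermal sheath against interfollicular dermis, and 119, 32, 19 and 37 specific to dermal stem cells, dermal sheath, dermal papilla and interfollicular dermis. The follicle mean of dermal stem cells and dermal papilla gave 5931. Camera with an estimated correlation passed 0 lists, with 33 at an unadjusted p under 0.05. Fry passed 68, and 14 of the 71 calls made with the preset correlation were not among them. The R-spondin list in dermal papilla against dermal sheath turned from upward with camera to downward with fry (adjusted p = 0.046), and the hair matrix list in dermal papilla against dermal stem cells ranged from 8.16e-05 to 0.762 with one library left out, reversed without dermal papilla replicate 2. Where no cause is named, the cause was not tested. Of 484 called pairs of a named gene and a comparison, 402 kept their call under every alternative fixed beforehand, as did 23 of 32 named population-specific genes. The depth of the libraries is unknown in reads and limits what low values can show.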

Other observations

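All tests of explanations in this part, and the choice of the genes that set dermal sheath apart from interfollicular dermis, were made after the results were seen, while the counts over other splits of the samples were planned.

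The libraries labelled dermal sheath and interfollicular dermis differed in 289 genes, 120 higher and 169 lower in dermal sheath. Among the genes higher in dermal sheath, Fgf5, a signal that ends hair growth, averaged 8.38 ± 3.1 FPKM against 0.176 ± 0.187 (fold change 2.94, SE 0.44, adjusted p = 0.0045), Cntfr 104 ± 39.9 against 16 ± 6.07 (2.64), the Wnt receptor gene Fzd1 66.8 ± 19.8 against 11.2 ± 1.99 (2.45), the guidance gene Flrt2 22.5 ± 8.46 against 3.29 ± 0.588 (2.41) and Lgr5 23.2 ± 8.97 against 3.11 ± 0.271 (2.49). The transcription factor gene Creb5 (2.76, adjusted p = 0.0011) and Tagln (2.85, adjusted p = 0.014) were also higher. The interfollicular dermis side held the hair shaft gene Krt35 (8.38 ± 0.284 against 308 ± 55.4, -5.03), Shh (2.16 ± 0.861 against 65.1 ± 21.5, -4.36, adjusted p = 5e-05), Krt79 (-4.29), the melanocyte genes Mlana (-4.91) and Dct (-4.46) and the neutrophil gene S100a8 (-4.77). Without dermal sheath replicate 1, 4 or 5 the count was 167, 189 or 103, and without interfollicular dermis replicate 1 or 2 it was 114 or 163. The keratin genes of the inner root sheath Krt71 (chromosome 15, 101733949 to 101743097) and Krt25 averaged 436 ± 145 and 335 ± 42 in dermal sheath and 161 ± 14.2 and 199 ± 25.7 in interfollicular dermis. The common reference gene Gapdh was listed at 0 to 1.12 FPKM in every library, while Actb ran from 65.5 to 301.

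Transcripts of fibrillar collagens were few in the libraries labelled dermal sheath and interfollicular dermis, and the tables argue against the authors' scaling, since the median collagen fold change between dermal sheath and dermal stem cells was -3.82 with median-of-ratios scaling. They also argue against an exchange of interfollicular dermis with dermal stem cells, since 22 of 22 smooth muscle genes were higher in every dermal stem cell library, as was Acta2 (850 FPKM or more against 10.4 or less). An exchange of columns with dermal papilla is not decided. There 12 of 27 papilla genes lay above those 6 libraries in every dermal papilla library and 2 lay below. The interfollicular fibroblast list was higher too (4796 FPKM or more against 1157 or less), so a fall of mesenchymal genes as a group could also raise papilla genes there. An exchange of dermal sheath with dermal stem cells cannot be told apart from correct labels, since 11 of 13 sheath markers and 17 of 21 interfollicular fibroblast markers were higher in every dermal stem cell library, which an exchange and a fall of mesenchymal genes as a group would both give. Hair epithelium in these sorts is a candidate explanation: 11 of 39 tested epithelial genes (Krt5, Krt17, Trp63, Itgb4, Shh, Msx2, Dlx3, Hoxc13, Foxn1, Krt28 and Lhx2) lay above every dermal stem cell and dermal papilla library in all 6 libraries, and 2, Krt1 and Krt10, lay below. The keratinocyte list as a whole did not follow: it summed to 7194 and 7488 FPKM in dermal papilla replicates 1 and 2 and to at most 4510 in those 6 libraries. Much of these 2 papilla sums came from Krt10 (1960 and 2050) and Krtdap (2060 and 2290), so the sum says little about hair epithelium. The hair matrix list summed to 1221 to 1576 in those 6 libraries and to 236 to 582 in dermal stem cells. In dermal papilla replicates 1, 2 and 4 it summed to 423, 1422 and 149. Of the 39 genes 33 reached 1 FPKM in all dermal stem cell and dermal papilla libraries and 0 are in another list, and a gate that excludes epithelial cells would remove this source, but the antibodies are not named, and a difference between the dermal populations themselves was not tested.

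Macrophage genes were high in dermal stem cells replicates 1 and 2, where the immune list summed to 3740 and 2077 FPKM against 127 in replicate 4, a factor of 22.9, and replicate 1 was highest in dermal papilla (1615, 873 and 576 in replicates 1, 2 and 4) and dermal sheath (797, 69 and 59 in replicates 1, 4 and 5) but not in interfollicular dermis (151, 216 and 402 in replicates 1, 2 and 6). The tables argue against a lower share of the sorted cell type as the whole cause, since it would raise markers of other cells alike and the median factor of the 8 other lists of other cells was 1.71 (range 1.17 to 3.37). Leukocytes in these 2 libraries cannot be told apart from a change in the sorted cells, since 21 of 21 tested immune genes higher in both than in replicate 4 restates the pattern, with the most abundant C1qb at 714 and 271 against 19.8 and C1qa at 628 and 235 against 13. Of the 21 genes 15 reached 1 FPKM in replicate 4 as well and 0 are in another list. What libraries of one number share, such as an animal, a day or a sort, stays open, since the labels give none of these.

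Papilla markers were highest in dermal papilla replicate 4, where the list summed to 3028 FPKM against 567 and 999 in replicates 1 and 2. A higher share of papilla cells in this library may account for part of it: 9 of 9 lists of other cells had a lower sum there than the mean of replicates 1 and 2, with ratios from 0.162 for hair matrix to 0.846 for Schwann cell genes. The papilla list itself stood at a ratio of 3.87. The shift is not particular to this library: in dermal stem cells the papilla list also stood highest in replicate 4 (543, 473 and 1062 in replicates 1, 2 and 4), and all 9 lists of other cells had a lower sum there than the mean of replicates 1 and 2. What these libraries of one number share, such as an animal and its stage of the growth cycle, a day or a sort, stays open, since the labels give none of these.

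Other splits of the samples were counted for each comparison. For pairs of populations there are 10 splits of 6 libraries, too few for a share under 0.05: dermal papilla against dermal stem cells gave 1110 genes and the highest other split 4, dermal sheath against dermal stem cells 5607 and 13, dermal papilla against dermal sheath 6365 and 2, and against interfollicular dermis dermal stem cells gave 4800 and 0, dermal sheath 289 and 2, and dermal papilla 5400 and 2. Of 100 regroupings of the 12 libraries, the real one included, 1 gave as many genes for the F test (7256, highest other 468), for follicle against interfollicular dermis (3384, highest other 5), for dermal stem cell genes (451, highest other 2) and for interfollicular dermis genes (75, highest other 1). For genes specific to dermal sheath (68, highest other 128) and dermal papilla (173, highest other 184) 2 of 100 did. Most regroupings mix unlike populations, which widens the spread within groups. They therefore argue only against 12 interchangeable libraries, and cannot tell whether a single one of these counts arose by chance.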
